A study of Homo sapiens with 2 samples.

How the data were processed

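Single-cell RNA sequencing with CellPlex tags (10x Genomics cholesterol-anchored oligonucleotides) was carried out on 1 pooled library of 5 MCF7 cultures, deposited as a gene expression sample and a tag sample of the same cells. The deposited matrix holds UMI counts per feature and barcode that the authors produced with Cell Ranger 7.1.0, per the file headers, and the submitters' processing notes name Cell Ranger, Seurat and the build GRCh38 (hg38). The annotation release behind the gene names is not given in the sources used here. The matrix is not filtered: it holds 36601 genes and 12 tags over 3490264 barcodes, with 549048059 gene UMIs and 180814001 tag UMIs. The labels name 1 tag per culture for 5 of the 12 tags, and the 7 others together held 6486 UMIs.

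From these counts, cells were called with the order-of-magnitude rule of Cell Ranger on gene UMIs (threshold 9218.04 UMIs, 13102 barcodes). Cells needed at least 500 genes, which removed 0, and at most 20% of UMIs from mitochondrial (MT-) genes, which removed 329. For each tag a Gaussian mixture of 2 components was fitted to log10 tag UMIs plus 1, and a cell was positive at a posterior of at least 0.9 for the upper component. Cells positive for exactly 1 tag were assigned (60.0% of kept cells), cells with more than 1 tag were left out as multiplets (4.80%), and cells with none were left out (35.2%). The cells with no tag had a median of 31212 UMIs and the multiplets 49284. Doublets within 1 culture carry 1 tag and stay in. Scrublet, as run through scanpy, called 0 of 12773 cells, which includes 0% of the tag multiplets, and so did not work here. The reason was not tested.

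UMIs were summed per culture and divided by the total of all genes to give CPM. Ratios between cultures are log2 ratios of CPM with 0.5 added to each summed count. Folds are ratios of CPM with nothing added. A gene counted as measured in a comparison with at least 100 UMIs and at least 10 CPM in at least 1 of the cultures compared, which left 9116 to 9320 genes against parental, and the distance used genes with at least 50 CPM in at least 1 culture. The median log2 ratio of all measured genes lay between -0.03 and 0.04 against parental. Named genes followed a rule of size fixed before the data were examined: the 12 highest and 12 lowest ratios per culture against parental, the 12 per direction with the largest smallest ratio among genes at least 2-fold different in all 4 organ-derived cultures, the 10 per culture and direction at least 2-fold from each of the 4 other cultures, the 8 highest and 8 lowest against mammary, ESR1, and members of the fixed gene lists that were measured and at least 2-fold different from parental. B2M, PSMB9, TAP1 and other list members were named under the last part. MT- genes, ribosomal protein genes and rows without a usual gene symbol were left out of naming, as were XIST and Y-linked genes. The 29 gene lists were fixed at the same time, and all 663 entries were found among the gene names. A list with fewer than 3 measured members has no median. Its percentile among 10000 random lists, drawn from 20 bins of mean expression, describes these cultures and is no test. Gene positions come from GENCODE 29 on GRCh38, in which 94.6% of the gene identifiers were found.

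Intervals are exact at 95%: Poisson for summed counts, Clopper-Pearson for shares and conditional binomial for ratios. They cover counting error only and say nothing on the spread between cultures of 1 origin, because each origin is 1 culture. The pool went through droplets together, so free RNA of 1 culture adds UMIs to cells of the others. Reads of a gene and of an overlapping or antisense gene, such as CD27-AS1, and of close copies, such as the HLA class I genes, may have been counted on each other, since the counting is described no further in the sources used here. The builds named are human alone, so reads of mouse cells, if any, were not separated.

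Other settings chosen at the same time were a floor of 3000 UMIs for cells, HTODemux of Seurat 5.3.0 at its quantile of 0.99, a top-share tag rule (at least 80% and 20 UMIs), MT- limits of 10% and none, thinning to 10000 UMIs per cell, subtraction of the profile of droplets under 100 UMIs at 5%, TMM scaling (edgeR 4.0.16), the cells in the lower part of the cycling share, and other minimums of CPM. Added after the data were seen were leaving out cells with 10 or more stroma list UMIs, subtracting the profile of droplets with 800 to 1600 UMIs, and leaving out the tenth of cells with the most UMIs. Gene ratios were tested on simulated data for each comparison with parental: all 200 genes changed by 2- or 4-fold among the 9320 of the lung comparison had the right direction, and 94.6% of the intervals of 500 unchanged genes held the true ratio. In the bone comparison 93.4% of the intervals did. The simulated counts were Poisson, as the intervals assume, so this checks the computation and not the spread of the real counts. Tag calling was tested on 12773 simulated cells, of which 97.9% were assigned, 100% of them to the right culture. Each simulated cell carried exactly 1 tag, and no untagged cells or multiplets were simulated. The simulation therefore does not show how well the real cells, many of them without a clear tag, were assigned. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5 and matplotlib 3.10.9, and R 4.3.3.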

Results

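The gene expression of MCF7 cells, an estrogen receptor positive luminal breast cancer line that carried luciferase and red fluorescent protein (RFP), was measured by single-cell RNA sequencing in 5 cultures. The parental culture was set beside 4 cultures regrown from organs of nude mice that had been injected in the iliac artery and in the mammary fat pad: mammary, bone, lung and ovary. The cultures had been expanded in vitro and sorted on RFP, labelled with 1 lipid-anchored oligonucleotide tag each and pooled into 1 library. Each origin was 1 culture, so no difference has a replicate check, no test between origins was possible, and every interval is an exact 95% interval that covers counting error only.

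Of 12773 cells kept, 7659 carried exactly 1 tag and entered the comparisons, 613 carried more than 1 and 4501 carried none. The parental culture had 1057 cells (13.8% of the assigned cells, exact interval 13.0 to 14.6), mammary 1935 (25.3%, 24.3 to 26.3), bone 676 (8.83%, 8.20 to 9.48), lung 2190 (28.6%, 27.6 to 29.6) and ovary 1801 (23.5%, 22.6 to 24.5). The depth was 33089726 gene UMIs (unique molecular identifiers, here counted molecules) in parental, 72981870 in mammary, 23870640 in bone, 78128294 in lung and 64599844 in ovary. The median cell held 25029 UMIs in parental, 33442 in mammary, 30666 in bone, 31374.5 in lung and 31220 in ovary. The bone tag separated least from its background, with component means of 1050 against 139 tag UMIs, and the number of bone cells was 1373 with HTODemux and 282 with the top-share rule.

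The first comparison asked how far the transcriptome of each organ-derived culture stood from the parental culture. Bone lay nearest to parental, with a root mean square log2 ratio of 0.479 over 3532 genes, followed by mammary at 0.515, ovary at 0.563 and lung at 0.633. Mammary, lung and ovary lay closer to each other than to parental, at 0.312 between ovary and mammary, 0.355 between ovary and lung and 0.404 between lung and mammary. Bone stood apart from these 3 cultures, at 0.494 from mammary, 0.582 from ovary and 0.594 from lung. Random equal splits of the cells of 1 culture lay 0.0602 to 0.109 apart over the same genes.

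**Figure D1:**
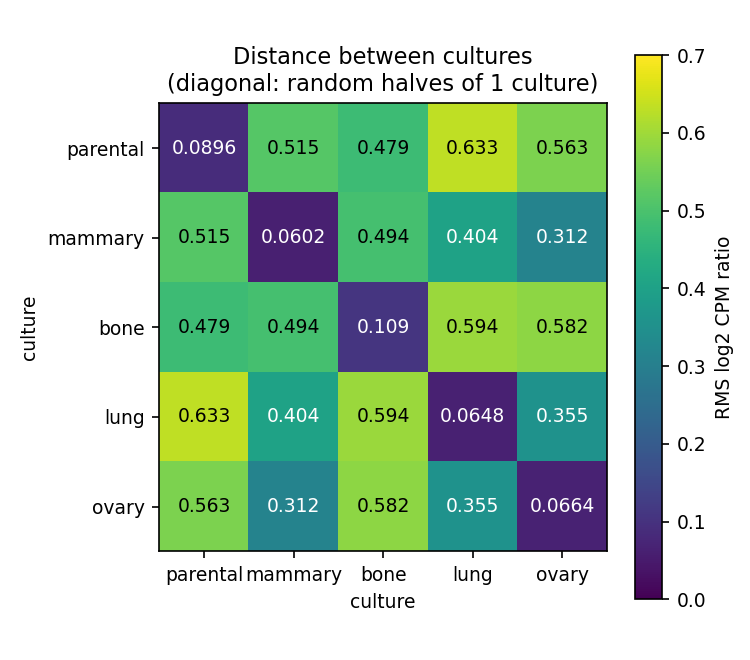
Heat map of the root mean square log2 CPM ratio for each pair of cultures, with both axes listing the 5 cultures, the colour giving the distance and the diagonal giving the distance between random equal splits of the cells of 1 culture. Mammary, lung and ovary lie 0.312 to 0.404 from each other, and all 4 organ-derived cultures lie 0.479 to 0.633 from parental.

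Genes that separated all 4 organ-derived cultures from parental were next taken by size. MDK, which encodes the heparin-binding growth factor midkine (ENSG00000110492, chromosome 11, 46380756 to 46383837, GRCh38), stood at 244 CPM (the count scaled to a common total of UMIs per culture) in parental and was 33.3-fold lower in mammary (exact interval 30.5 to 36.4), 44.8-fold lower in bone (37.7 to 53.7), 22.9-fold lower in lung (21.3 to 24.6) and 23.4-fold lower in ovary (21.7 to 25.4). DPYD, the first enzyme of pyrimidine breakdown, was 12.7- to 22.9-fold lower, and NR3C1, the glucocorticoid receptor, went from 17.6 CPM in parental to 2.01 in mammary, 1.21 in bone, 2.48 in lung and 2.14 in ovary. SYT10, a synaptotagmin, went from 79.7 CPM in parental to between 6.83 and 11.8 CPM, and CA2, a carbonic anhydrase, from 55.6 to between 4.90 and 10.5 CPM. C8orf88, HS3ST3A1, ZNF804B, UGT2B15, RORA, SHH and the antisense gene CD27-AS1 belonged to the same group of lower genes. In the other direction SYT17 was 3.38- to 5.02-fold higher, the hair keratin KRT81 was 6.43-fold higher in mammary (5.89 to 7.03), 2.74-fold in bone (2.47 to 3.04), 3.13-fold in lung (2.86 to 3.43) and 5.94-fold in ovary (5.44 to 6.50), and DNALI1 was 2.93- to 4.21-fold higher. HCK, a Src family kinase, and L1CAM, a cell adhesion molecule, were higher by 3.08- to 3.35-fold and by 2.34- to 2.85-fold. All 4 ratios share the same parental culture, so a property of that culture enters each of them.

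Interferon-stimulated genes set lung and ovary apart from the other cultures. In lung 33 of 34 measured members were higher than in parental, with a median log2 ratio of 2.45, and in ovary 33 of 34 were higher, with a median of 2.20. In mammary 27 of 29 were higher, with a median of 0.70, while in bone 21 of 26 were lower, with a median of -0.32. A member measured in lung, ovary or mammary but not in bone passed the minimum CPM only through that culture. Such a member could only count as higher. The medians of lung, ovary and mammary stood at percentile 100 of 10000 random lists of the same size and expression, and that of bone at percentile 0. ISG15, a ubiquitin-like protein induced by interferon, stood at 465 CPM in parental, 810 in mammary, 388 in bone, 2756 in lung and 2513 in ovary. IFI27 was 7.40-fold higher in lung (7.28 to 7.52) and 5.38-fold in ovary (5.29 to 5.47), and the transcription factor STAT1 3.78-fold (3.65 to 3.91) and 3.61-fold (3.49 to 3.74). IFI44L was 15.3-fold higher in lung (13.4 to 17.6) and 4.65-fold in ovary (4.05 to 5.38). ISG20, against most of the list in mammary and with it in bone, had log2 ratios of -1.70 and -2.48. Against mammary, the list median was 1.62 in lung, 1.43 in ovary and -1.08 in bone. The bone median against parental was -0.64 with HTODemux tag calls and -0.71 in the cells with the lower cycling share. Relative to droplets with 800 to 1600 UMIs, which hold free RNA of the pool, the list median was 0.94 in lung, 0.89 in ovary, -0.65 in mammary, -1.28 in parental and -1.61 in bone, a comparison chosen after the data were seen. These medians cover 34 members in lung and ovary, 29 in mammary and 26 in parental and bone. The ranges over resampled genes of parental (-1.79 to -0.86) and bone (-1.99 to -1.32) overlapped.

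Genes of antigen presentation by MHC class I followed the same cultures. All 11 members measured in lung were higher than in parental, with a median log2 ratio of 1.54, and so were all 11 measured in ovary, with a median of 1.22, both at percentile 100. The medians were 0.15 in mammary (9 measured members, percentile 69.8, 0.03 with HTODemux) and -0.04 in bone (7 measured members, percentile 29.5). The members measured in lung or ovary but not in bone passed the minimum CPM only through lung or ovary, so they could only count as higher. B2M, the light chain of the MHC class I molecule, was 2.47-fold higher in lung (2.43 to 2.51), 2.23-fold higher in ovary (2.19 to 2.26) and 1.49-fold lower in bone (1.46 to 1.53). The immunoproteasome subunit PSMB9 was 8.33-fold higher in lung (7.33 to 9.50) and 5.21-fold in ovary (4.57 to 5.96), and the peptide transporter TAP1 4.51-fold (3.92 to 5.20) and 4.49-fold (3.90 to 5.19).

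**Figure D2:**
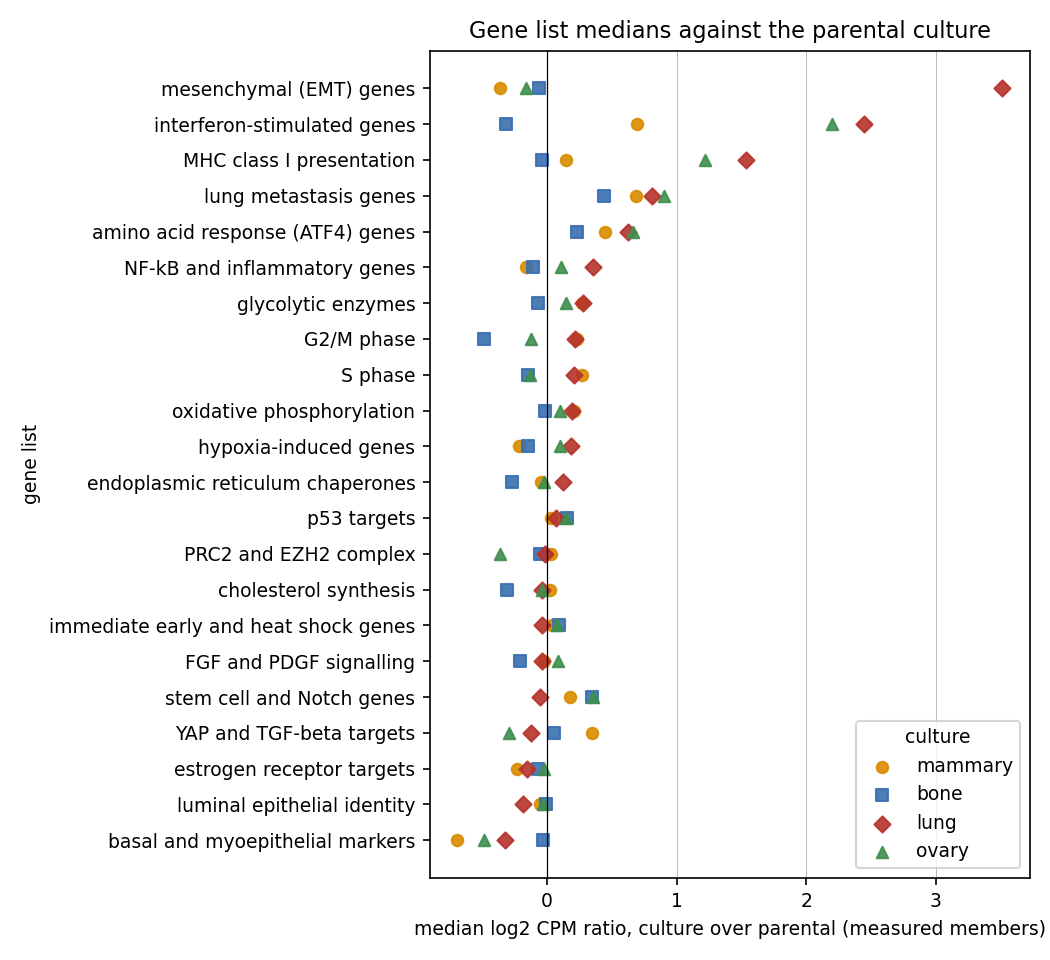
Median log2 CPM ratio over parental of the measured members of each gene list (x axis) for the lists with a value in all 4 organ-derived cultures (y axis), with 1 symbol per culture. The interferon-stimulated list lies at 2.45 in lung and 2.20 in ovary against -0.32 in bone. The mesenchymal list lies at 3.52 in lung, and at 0.07 there over the members still measured without the cells that hold stromal UMIs.

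Estrogen response differed by gene more than as a group. ESR1, the estrogen receptor gene, stood at 450 CPM in parental and 446 in bone, and was 1.37-fold lower in mammary (1.34 to 1.39), 1.31-fold lower in lung (1.28 to 1.34) and 1.42-fold lower in ovary (1.39 to 1.45). The median log2 ratio of the estrogen receptor targets was -0.23 in mammary (19 of 43 members higher, percentile 0.02), -0.15 in lung (17 of 42, percentile 0.1), -0.07 in bone (19 of 43, percentile 2.79) and -0.03 in ovary (20 of 41, percentile 24.9). In the cells of lower cycling share the median was -0.04 in mammary, -0.09 in lung, -0.01 in bone and 0.05 in ovary, and with TMM scaling it was 0.11 in ovary and -0.17 in bone. TFF1, a secreted trefoil peptide and a classical estrogen target, was 4.76-fold lower in bone (4.72 to 4.80) and 1.25-fold higher in ovary (1.24 to 1.25). AREG, an EGF receptor ligand, was 7.58-fold lower in bone (7.14 to 8.06) and 2.95-fold lower in lung (2.87 to 3.03). CXCL12, a chemokine, was 2.88-fold higher in bone (2.74 to 3.02) and 2.41-fold lower in ovary (2.27 to 2.56), and SUSD3 was 5.54-fold higher in mammary (4.89 to 6.30). Luminal identity genes had medians of -0.05 in mammary, -0.01 in bone, -0.18 in lung and -0.03 in ovary, the last of which was 0.08 with TMM scaling.

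Genes that set bone apart from all 4 other cultures came next. The receptor tyrosine kinase KIT was 7.88-fold higher than in parental (6.16 to 10.2), the neuregulin NRG3 4.84-fold (4.52 to 5.20), MYRIP 7.40-fold (6.14 to 8.99) and OLFML3 9.04-fold (8.20 to 9.98), and each stood at least 2-fold above all 4 other cultures. ANKRD1, a target of YAP signalling, was 15.1-fold higher (9.86 to 24.3), from 0.695 to 10.5 CPM, just above the minimum of 10 CPM. It was also higher in lung at 7.26 CPM, under that minimum, so it did not count as measured there. SLPI, a protease inhibitor, was 9.28-fold lower in bone than in parental (6.35 to 14.0), the surface protein CD109 9.62-fold (7.23 to 13.1) and the prohormone processing enzyme CPE 3.74-fold (2.86 to 4.96). Against mammary, SOX6, EPHA7 and CAV1 were among the 8 highest genes of bone: SOX6 stood at 36.5 CPM against 2.84, EPHA7 at 20.9 against 2.21, and CAV1, a coat protein of caveolae (chromosome 7, 116524785 to 116561184), at 402 against 48.1. These 3 genes stood at 22.3, 12.3 and 220 CPM in parental.

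Mammary and ovary had few genes of their own. ASCL1, a neuroendocrine transcription factor, was 20.2-fold higher in mammary than in parental (15.7 to 26.4), at 37.8 CPM, against 9.43 in ovary, 6.03 in lung and 2.30 in bone. WLS, a carrier of Wnt ligands, was 4.22-fold lower in mammary than in parental (3.46 to 5.17). The calcium-binding proteins S100A8 and S100A9 were 12.6-fold (10.6 to 15.1) and 7.77-fold (7.09 to 8.52) higher in ovary than in parental, and 5.29-fold (4.42 to 6.36) and 3.76-fold (3.42 to 4.13) higher in mammary. SELENOP and AHNAK2 were the other genes at least 2-fold higher in ovary than in all other cultures, and the potassium channel KCNJ3 was 13.4-fold lower there than in parental (12.2 to 14.8).

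**Figure D3:**
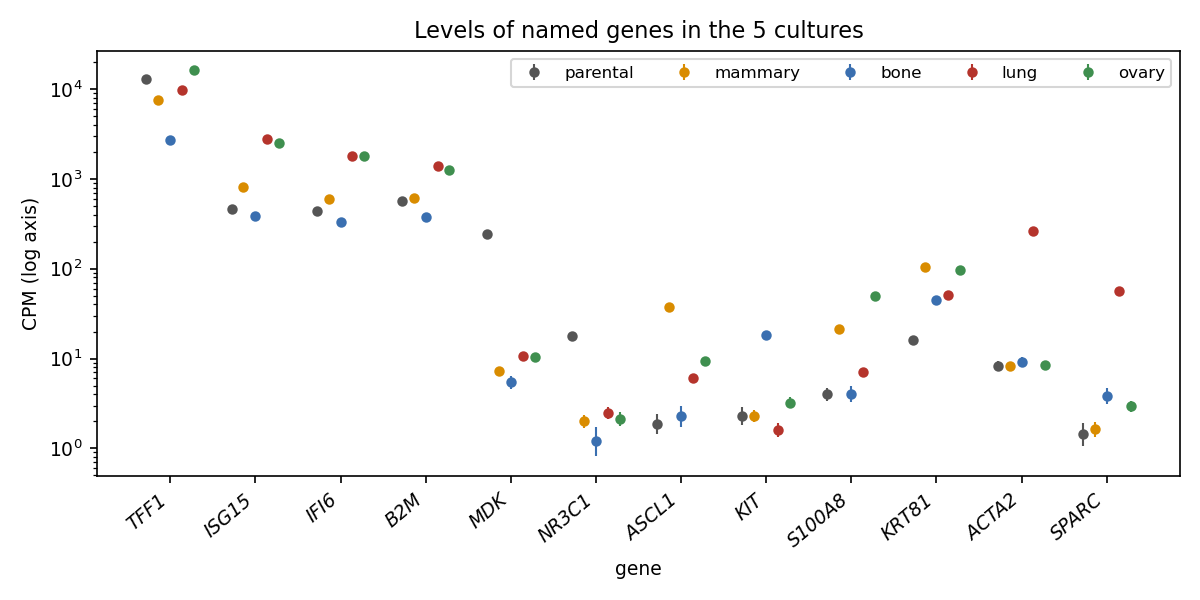
CPM on a log axis (y) of 12 named genes (x) in the 5 cultures, with exact Poisson 95% intervals of the summed counts as bars. MDK stands at 244 CPM in parental and at 5.45 to 10.7 CPM elsewhere, ISG15 is highest in lung and ovary, KIT in bone, ASCL1 in mammary, and ACTA2 and SPARC in lung.

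Among the 12 highest genes of lung over parental were several of stromal and contractile cells. The matrix protein SPARC was 38.8-fold higher than in parental (29.2 to 52.7), the smooth muscle actin ACTA2 31.5-fold (28.0 to 35.6), the collagen gene COL1A2 28.5-fold (20.7 to 40.4) and the actin-binding protein CALD1 22.2-fold (15.7 to 32.3). The mesenchymal list had a median log2 ratio of 3.52 in lung, with 6 of 7 measured members higher. It was -0.37 in mammary (3 measured members), -0.07 in bone (4) and -0.17 in ovary (4). These UMIs came from few cells: 105 of 2190 lung cells (4.79%, exact interval 3.94 to 5.77) held 10 or more UMIs of the 12-gene stroma list, against 2 of 1057 parental, 0 of 1935 mammary (which allows a share of up to 0.155%, taken as 3 counts), 2 of 676 bone and 4 of 1801 ovary cells. So did 210 of the 4501 cells with no clear tag (4.67%, 4.07 to 5.32) and 6 of the 613 multiplets, which entered no culture. The lung tag was the highest tag in 189 of these 216 cells (87.5%) and in 1728 of the 4898 other cells without 1 clear tag (35.3%), a comparison chosen after the data were seen, and it had the highest background of the 5 tags. Without these cells, as computed after the data were seen, the lung log2 ratio over parental was 1.61 for ACTA2 in place of 4.97, 2.18 for SPARC in place of 5.26 and 0.86 for COL1A2 in place of 4.82, and the mesenchymal list median was 0.07. That median is over the members still measured: SPARC, at 6.10 CPM in the other lung cells, fell under the minimum CPM. The list of lung metastasis genes had a median of 0.81 in lung, and of 0.07 over the members still measured without the cells holding stroma UMIs. It was 0.69 in mammary, 0.44 in bone (0.13 with HTODemux) and 0.90 in ovary. With no minimum CPM the median of this list was 0.22 in lung, 0.40 in mammary, 0.04 in bone and 0.09 in ovary. The interferon median of lung was 2.48 without the cells holding stroma UMIs.

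Amino acid response genes, which ATF4 drives, had higher medians in lung, ovary and mammary than in parental. Their median log2 ratio was 0.62 in lung and 0.66 in ovary (both percentile 100), 0.45 in mammary (percentile 99.98) and 0.23 in bone (percentile 98.1), with 14 of 17 measured members higher in lung, 15 in ovary, 14 in mammary and 12 in bone. The bone median was 0.12 with HTODemux, 0.08 after thinning and 0.06 in the cells of lower cycling share. The stress regulator NUPR1 had log2 ratios of 1.40 in mammary, 1.09 in bone, 2.13 in lung and 2.19 in ovary. SLC7A5, a transporter of large amino acids, had ratios of 1.79 in mammary, 0.04 in bone, 1.29 in lung and 2.15 in ovary. DDIT4 was 2.10-fold higher in lung (1.97 to 2.24) and 3.17-fold in ovary (2.97 to 3.38). VLDLR, a lipoprotein receptor, went the other way, at -1.73 in mammary, -1.26 in bone, -0.81 in lung and -1.44 in ovary.

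Cell cycle genes took the smallest share of UMIs in bone and ovary. The S phase and G2/M lists together took 0.632% of UMIs in parental, 0.691% in mammary, 0.488% in bone, 0.703% in lung and 0.561% in ovary. The G2/M list alone took 0.327% in bone (exact interval 0.325 to 0.329) and 0.449% in parental (0.447 to 0.452). Of the 54 G2/M genes, 53 were lower in bone than in parental (median log2 ratio -0.49, percentile 0, and -0.26 with HTODemux), 38 were lower in ovary (-0.12, percentile 5.48), 40 were higher in lung (0.22, percentile 99.3) and 38 were higher in mammary (0.23, percentile 99.9). With TMM scaling the ovary median was -0.02. After each cell was thinned to 10000 UMIs, the G2/M share was 0.419% in parental, 0.459% in mammary, 0.300% in bone, 0.470% in lung and 0.375% in ovary. Thinning left out 21 parental, 11 mammary, 7 bone, 18 lung and 9 ovary cells.

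Ratios over parental also varied along the chromosomes, a comparison chosen after the data were seen. Over 191 blocks of up to 50 neighbouring measured genes, centred on the median of all genes, the lowest values shared by the 4 organ-derived cultures lay on chromosome 12 between 12715058 and 42144879 (GRCh38), with block medians of -0.51 in mammary, -0.55 in bone, -0.55 in lung and -0.53 in ovary. On chromosome 7 between 102473118 and 123558255 the medians were -0.79 in mammary, -0.78 in lung and -0.75 in ovary, against -0.12 in bone. In that stretch 47, 46 and 48 of 50 genes lay below the median of all genes in mammary, lung and ovary, and 33 of 50 did in bone. CAV1 lies in this stretch. Other blocks also differed between the organ-derived cultures. On chromosome 1 between 16246839 and 25500209 bone lay at 0.42, against 0.01 in mammary, -0.01 in lung and -0.03 in ovary. On chromosome 14 between 45203190 and 57298742 lung and ovary lay at 0.19 and 0.16, against -0.22 in mammary and -0.13 in bone.

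**Figure D4:**
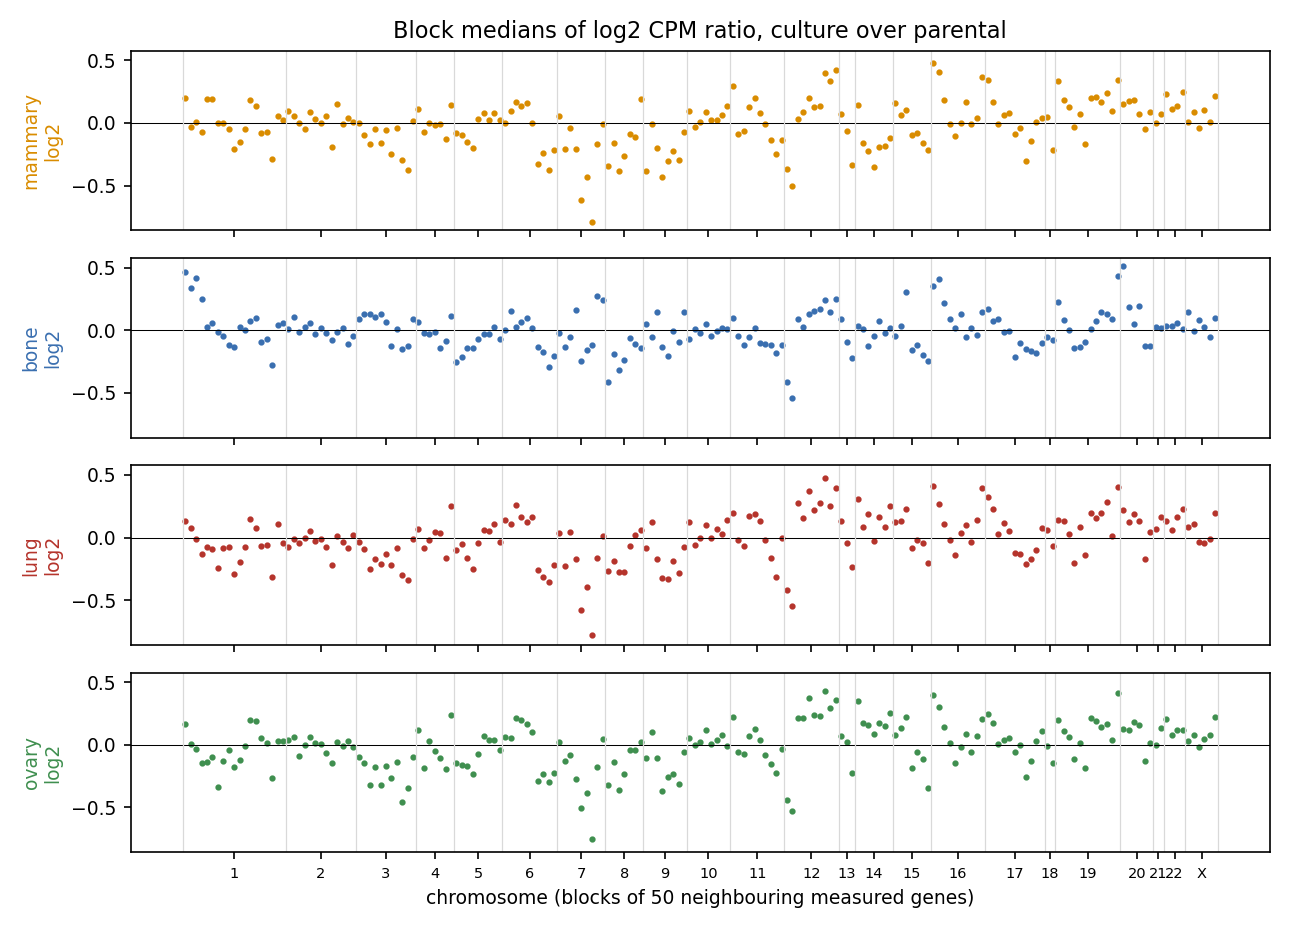
Median log2 CPM ratio over parental, centred on all genes (y axis), for 191 blocks of up to 50 neighbouring measured genes in genome order (x axis, chromosomes 1 to 22 and X), with 1 panel per culture and 1 point per block. The chromosome 12 block at -0.51 to -0.55 is low in all 4 panels, and the chromosome 7 block at -0.75 to -0.79 in mammary, lung and ovary stands at -0.12 in bone.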

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

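The tests of the stromal cells on their median epithelial and median mitochondrial shares were chosen after the result was seen. So were the comparisons without those cells and the test of free RNA. The median mitochondrial share took the place of the summed share, 2.57% against 7.03%, which had decided nothing. The range of the summed epithelial share over resampled cells was added after its value was seen. The other tests had their bounds set before. Differences between cultures were not tested, since each origin is 1 culture.

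Stromal transcripts were not a planned measurement: 4.79% of the cells of the lung culture carried 10 or more UMIs of the stroma list. The mesenchymal list median over parental was 3.88 higher in lung (7 measured members) than in mammary (3), with the medians on opposite sides of 0. Taken directly over mammary, the lung median was 2.96 over 7 members. In the stromal cells ACTA2 stood at 6747 CPM, SPARC at 1430 and COL1A2 at 885, against 24.6, 6.10 and 1.62 CPM in the other lung cells.

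Doublets of an MCF7 cell with a stromal cell are argued against as the source of these cells as a group, since their median UMIs were 0.618 times those of the other lung cells, but not for the 39 of 105 cells with more epithelial UMIs, whose median of 38375 UMIs lay above the 31938 of the other lung cells. The summed epithelial marker share of the 105 cells was 0.508 times that of the others (0.413 to 0.599 over resampled cells). It met the bound of 0.5 set beforehand against cells of another type, but the range over resampled cells, added later, crossed that bound. Cells of another type therefore stay open on this share, in which the deepest droplets weigh most. The median cell had 0.263 times the epithelial share of the others, so cells of another type, part of them in 1 droplet with an MCF7 cell, may be the source. Mouse host cells, whose mitochondrial reads match the human sequence poorly, are a candidate for such cells of another type. The median mitochondrial share was 0.0884 times that of the others (0.593% against 6.72%). The share on clone-named genes, looked at as a sign of mouse reads, was 0.895% against 0.831%. The cultures had been sorted on RFP, but the purity of the sort is not known here, so it does not decide on cells without the label. A change of MCF7 cells themselves was not tested.

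Interferon-stimulated genes had a median over parental 2.76 higher in lung (34 measured members) than in bone (26), again on opposite sides of 0. The members measured in lung but not in bone passed the minimum CPM only through lung, so they could only count as higher. A minority of cells, or the stromal cells, are argued against: after thinning, 99.03% of the lung cells without stroma UMIs and 99.16% of the ovary cells lay above the parental median. After thinning, the medians were 2.54 in lung and 2.36 in ovary. CPM is already scaled to total UMIs, so thinning could hardly have lowered these medians and does not decide on depth. Depth is argued against by bone, which had a median of 30666 UMIs per cell against 31374.5 in lung and the opposite sign. Free RNA is argued against in lung and ovary, whose list medians stood 0.94 and 0.89 (log2) above droplets with 800 to 1600 UMIs. Parental, mammary and bone stood below those droplets, so free RNA stays open for the smaller differences of mammary and bone from parental. The organ of origin, chance differences between cultures and conditions of regrowth stay open, untested, with 1 culture per origin.

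The YAP and TGF-beta target list median was 0.65 higher in mammary (0.35) than in ovary (-0.29), with opposite signs; 6 of 11 members were higher in mammary and 6 of 11 lower in ovary, and the ovary median was 0.055 with TMM scaling and 0.19 at the lower minimum CPM.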

How the results depend on the processing

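Leaving out the stromal cells, subtracting the profile of droplets with 800 to 1600 UMIs and leaving out the tenth of cells with the most UMIs were chosen after seeing the data, and the others before. No replicate can be left out, since each origin is 1 culture, and Scrublet called no cell, so removing its calls gave no value. Of 60 recomputed distances 31 lay within their spread over genes, of 50 cycling shares 40 within their spread over cells, of 2364 list medians 2281 within their spread over genes, and of 7200 gene ratios 5159 within their counting interval. Under each alternative run on the distances bone had the smallest distance from parental and lung the largest, but with HTODemux bone (0.480) and mammary (0.491) lay close. The cause of a shift was not tested unless stated. TMM scaling moved every log2 ratio over parental by 0.11 in ovary and by -0.07 in bone.

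The cells assigned to parental, cells assigned to mammary, cells assigned to bone, cells assigned to lung and cells assigned to ovary numbered 1057, 1935, 676, 2190 and 1801 in this order. With the floor of 3000 UMIs the first 4 were 1170, 2039, 555 and 2392. HTODemux gave 1200, 2088, 1373, 2359 and 2034, the top-share rule 908, 1153, 282, 2400 and 1173, and the limit of 10% mitochondrial UMIs 871, 1457, 507, 1822 and 1311. Without that limit mammary had 2013.

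Distances from parental in the order mammary, bone, lung and ovary were 0.515, 0.479, 0.633 and 0.563. They were 0.564, 0.521, 0.739 and 0.617 with the top-share rule, 0.551, 0.514, 0.684 and 0.604 after subtracting droplets under 100 UMIs, 0.551, 0.514, 0.687 and 0.598 after subtracting those with 800 to 1600 UMIs, 0.554, 0.530, 0.702 and 0.598 in the cells of lower cycling share, and 1.08, 1.02, 1.15 and 1.08 with no minimum CPM, where genes of few counts enter. For mammary, lung and ovary they were 0.555, 0.711 and 0.616 after thinning and 0.546, 0.674 and 0.599 without the cells of most UMIs. Mammary and ovary were at 0.546 and 0.602 with 2 times the minimum CPM, and mammary was at 0.491 and bone at 0.480 with HTODemux.

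The interferon list median was 2.71 in lung, 2.72 in ovary and 0.93 in mammary with the top-share rule, 0.55 in mammary and -0.64 in bone with HTODemux, and -0.71 in bone in the cells of lower cycling share. The estrogen target medians stayed within their spread over genes. The cycling share was 0.595%, 0.660%, 0.459%, 0.652% and 0.513% after thinning (parental, mammary, bone, lung, ovary), 0.715% in mammary with the top-share rule, 0.712% in mammary and 0.724% in lung at 10% mitochondrial UMIs, 0.526% in bone with HTODemux and 0.541% in ovary without the cells of most UMIs.

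List medians nearer to 0 than 0.25 changed sign in several settings, among them that of the estrogen targets in ovary. Of list medians of at least 0.25 and log2 gene ratios of at least 1 in size, these changed sign. The basal list over parental went to 0.055 in mammary with no minimum CPM, and in lung to 0.067 with the top-share rule, 0.026 after thinning, 0.13 in the cells of lower cycling share, 0.031 at the lower minimum CPM and 0.21 with none. The mesenchymal list went to 0.013 in mammary with no minimum CPM, and for bone over mammary to -0.079 at the higher minimum CPM and -0.058 with none. The YAP and TGF-beta list in ovary went to 0.055 with TMM and 0.19 at the lower minimum CPM and with none. MFAP5 in mammary went to 0.015 with the top-share rule, SPARC in bone to -0.32 with HTODemux and -0.38 in the cells of lower cycling share, SPARC in ovary to -0.77 and TMEM246 in bone to -1.14 with HTODemux.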

Other observations

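The tests of neighbouring genes, gene length and MDK had their bounds set before the result of each was seen, but the question and the stretches on chromosomes 7 and 12 were chosen after the gene ratios were seen, and so was the range over resampled genes. Cholesterol synthesis genes were lower in bone, with a median log2 ratio over parental of -0.31 and 16 of 22 members lower, and lay at 0.02 in mammary, -0.04 in lung and -0.04 in ovary (0.066 with TMM scaling). Oxidative phosphorylation genes had medians of 0.21 in mammary, 0.19 in lung, 0.10 in ovary and -0.01 in bone, with 32 of 35 members higher in mammary. Their percentiles among random lists of like expression were only 93.2, 88.8, 75.6 and 25.8 in this order. Chaperones of the endoplasmic reticulum were lower in 16 of 17 members in bone (median -0.27). The PRC2 complex, which places a repressive histone mark, had a median of -0.36 in ovary, with 9 of 10 members lower, against 0.03 in mammary, -0.06 in bone and -0.02 in lung (0.002 with TMM scaling). Stem cell and Notch genes had medians of 0.35 in bone, 0.35 in ovary, 0.17 in mammary and -0.06 in lung. Within this list the surface receptor CD44 had log2 ratios of -2.21 in mammary, -1.63 in bone, -2.91 in lung and -2.19 in ovary, while the BMP targets ID1 and ID3 had ratios of 1.57 and 1.77 in bone, 1.47 and 1.67 in ovary and 1.39 and 1.27 in mammary, against -0.07 and -0.28 in lung. Basal markers, with 6 to 9 genes measured, had medians of -0.69 in mammary, -0.03 in bone, -0.33 in lung and -0.49 in ovary, of which the lung and mammary values changed sign under other settings, to 0.067 in lung with the top-share tag rule and to 0.055 in mammary with no minimum CPM. In lung, where 9 basal markers were measured, the 3 higher ones were KRT17, TAGLN and ACTA2. ACTA2 stood at 6747 CPM in the lung cells with stromal UMIs and at 24.6 CPM in the others, so the former enter this list. CAV1 and its partner CAV2, in this list, had ratios of -2.20 and -1.80 in mammary, -2.56 and -2.69 in lung and -1.99 and -1.86 in ovary.

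Glycolytic enzymes had medians of 0.27 in mammary, 0.27 in lung, 0.15 in ovary and -0.07 in bone, and hypoxia-induced genes -0.22, 0.18, 0.10 and -0.15 in the same order. Medians of p53 targets (0.03, 0.07, 0.14 and 0.16) and of immediate early and heat shock genes (0.04, -0.04, 0.08 and 0.10) stayed near 0. Of the NF-kB list 5 genes were measured, with medians of -0.16, 0.35, 0.11 and -0.11, and of the FGF and PDGF list 5, with medians of -0.02 (0.019 with TMM scaling), -0.04, 0.08 and -0.21. Bone metastasis genes and fibroblast markers had 3 measured members in lung alone, with medians of 0.65 and 3.25. The fibroblast list is the one that defined the cells with stromal UMIs, and without those cells both lists had fewer than 3 measured members in lung. Markers of blood and lung epithelium had no measured gene in any culture, and those of endothelium, osteoblasts and ovarian cells had fewer than 3.

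Neighbouring genes differed together from parental more than shuffled genes did. The spread of block medians was 2.72 times that of shuffled genes on average over the 4 comparisons, as gains and losses of chromosome stretches would give, and it was 2.77 times after gene length and level were taken out, which argues against a trend on length. A candidate explanation is that copy number on chromosome 7 differs between bone and the 3 other organ-derived cultures. On the chromosome 7 stretch bone lay at -0.12 over parental and the 3 others at -0.75 to -0.79, which argues against a gain in bone alone there. A loss in the others stays open, with or without a gain in bone nearby, as neighbouring blocks of bone lay at -0.25 to 0.28. The chromosome 12 stretch may mark either all 4 organ-derived cultures or the parental one. Neighbours regulated together may add to the spread of block medians, and no DNA data were analysed here. Of the parental cells, 63.4% held a UMI of MDK after thinning, against 5.30% in mammary, 4.04% in bone, 7.14% in lung and 7.09% in ovary, where free RNA of the parental culture may give the lower shares. Cells without a UMI are not shown to lack MDK, so whether part of the parental culture, low in MDK, gave rise to the others stays open. The 251 parental cells without an MDK UMI lay at -0.0669 on the chromosome 12 stretch (-0.12 to 0.04 over resampled genes) against the 588 with 3 or more, short of the values of the organ-derived cultures, and at 0.12 on the chromosome 7 stretch. The value on the chromosome 12 stretch met the bound set beforehand against outgrowth, but its range over resampled genes, added later, crossed that bound. For this comparison 8 of the genes shared by the organ-derived cultures were picked by hand, without a rule, and no spread was computed. In the parental cells without an MDK UMI, 7 of the 8 differed in the direction of the organ-derived cultures. The log2 ratios were 1.92 for KRT81 and -1.48 for C8orf88, but only -0.15 for HS3ST3A1 and 0.25 for SYT17. NR3C1 went the other way at 0.61, so outgrowth of such cells stays open.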
